A study of Homo sapiens with 12 samples.

How the data were processed

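The data were gene expression microarrays of HCT116 cells, 12 arrays in 3 groups of 4: control siRNA, MYC siRNA1 and MYC siRNA2. Per the labels, cells were seeded 24 hours before transfection with 100 nM ON-TARGETplus siRNA and RNA was taken 48 hours after it, column-purified with DNase treatment, amplified and labelled with Cy3. The labels do not give the siRNA sequences.

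The authors deposited the output of the scanner software for each array, made with Agilent Feature Extraction 11.5.1.1 under the protocol named GE1_1105_Oct12 in the file headers. Per the file headers, the processed signal is an intensity on a linear scale, background-subtracted and spatially detrended within the array, with dim spots raised to a floor, and it is not normalised between arrays. The deposited median signal and local background of each spot are intensities as well, and the remaining columns used are other values, 0 or 1 marks for spots that were saturated, uneven or well above background. The authors' series table holds an intensity for each spot that equals the processed signal of the array times 1 constant per array, between 3.03 and 4.09, with a spread of at most 1.44e-09 on the log2 scale. The source of these constants is not stated.

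Each array held 62976 spots, 60901 of them not controls, for 58201 probes. Of these, 300 probes had 10 spots and 57901 had 1. Spots that the scanner software marked as uneven or as outliers among their replicates were dropped, the other spots of a probe were averaged on the log2 scale, and 103 probes without a usable spot on some array were left out. Probe accessions were looked up in a RefSeq gene table of assembly GRCh38.p14, used for names alone. Of 33080 probes with a RefSeq-style accession 31104 were named, giving 22439 gene symbols, and 27097 probes had no name. Of the named genes 6739 had more than 1 probe, and the probe with the highest mean over all arrays was used.

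The main values were the log2 processed signal minus the 75th percentile of the array. Genes were tested when their probe was well above background on all 4 arrays of at least 1 group, which left 14890. The model was limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with jsonlite 2.0.0 and the package data.table at 1.17.8, fitted to all 12 arrays with the group as the only term. Residual variances had 9 degrees of freedom and a prior of 1.75, and the median residual SD was 0.062. Genes were called at a Benjamini-Hochberg adjusted p below 0.05 in each of 3 comparisons: each MYC siRNA against control, and MYC siRNA2 against MYC siRNA1. MYC was also tested with an exact two-sided permutation test.

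Where no probe of a gene was well above background on any array of a group, the fold change is given as "at least", with the signal of each of these arrays raised to the lowest signal well above background on that array. Another detected probe of the same gene was called in the direction opposite to the brightest probe in 408, 533 and 756 of 3899 genes with several probes, for the 3 comparisons in that order.

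There were 32 gene lists, fixed with the other choices before the data were examined. Of 845 memberships in them, 833 were on the array and 778 were tested. They were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists, with camera at an estimated correlation and fry beside it. Genes to be named followed a rule set at the same time: the MYC network, the 10 largest shared rises and falls, the 5 largest changes per siRNA, the 8 largest differences between the siRNAs, and up to 4 members per list. The rule yields more genes than can be given here, and the subset named in the text was picked after the values were seen. CXCL8, CCL20, TNIP1, HMOX1 and the genes of 4 additional lists were also chosen after the values were seen.

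The labels do not say that arrays of the same replicate number belong together. After removal of the group means, arrays of the same number in different groups had correlations from 0.0048 to 0.069 across 13647 genes, those of other numbers from -0.096 to 0.051, and for 10 of 12 arrays the best match had the same number. A weak pairing is therefore possible, and a replicate block was fitted as an alternative. The pair differences within a group had an SD of 0.129 to 0.185, and probes with 10 spots varied between arrays of a group by 0.032 against 0.017 from spot noise alone, so that no array was a copy of another. The file headers placed the control arrays in row 1 and the MYC siRNA1 arrays in row 2 of slide 1, and the MYC siRNA2 arrays in row 1 of slide 2. A slide term could therefore not be fitted for MYC siRNA2, nor a row term for MYC siRNA1.

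The fit and the list test, without the steps from spots to genes, were tested on simulated data with 50 changed genes per size among 14890. Changes of 1.1-fold, 1.25-fold, 1.5-fold and 2-fold were recovered in 26%, 76%, 88% and 94% of genes for MYC siRNA1 against control, with 9 false calls among 14690 unchanged genes. For MYC siRNA2 against control the shares were 12%, 60%, 90% and 94% with 6 false calls, and for the comparison of both siRNAs 16%, 76%, 82% and 98% with 2. A list shifted by -0.2 was called in each, and 0 other lists were. The noise was drawn independently for each gene, so this does not show how the list test behaves with correlated genes. Few genes were changed, whereas 80.6% were called for MYC siRNA1 against control in the data. The adjusted threshold was therefore stricter in the simulation, and its shares and false calls do not carry over to the data.

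The alternatives tried were quantile normalisation, no scaling, median centring, the authors' scaled values, no filter or a strict filter on dim probes, the mean of all probes, a replicate block, 2-group fits, another variance model, an unmoderated test, stricter thresholds and leaving out each array. For the lists there were also an estimated correlation, fry and lists without shared members. Another 3 were chosen after seeing the data: the percentile over detected probes, scaling to 7 spike-in probes, and a normexp background correction with offset 50 on median signals. The planned normexp correction on mean signals could not be run, since the files hold no such column.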

Results

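Gene expression was measured on single-colour microarrays in HCT116 cells, a human colorectal carcinoma line, 48 hours after transfection with 100 nM of a small interfering RNA (siRNA). There were 3 groups of 4 arrays each, treated with a control siRNA, with MYC siRNA1 or with MYC siRNA2, and the study describes 4 independent experiments at each siRNA. Each array carried 62976 spots, of which 60901 were not controls. Between 45.6% and 50.7% of the non-control spots were well above background on an array, and 0 spots were saturated. The 75th percentile of the processed signal lay between 251 and 264 on the control arrays, between 256 and 264 with MYC siRNA1 and between 331 and 365 with MYC siRNA2. The number of arrays limits the precision. After naming and filtering, 14890 genes were tested, and 13647 of them were well above background on all 12 arrays. The control and MYC siRNA1 arrays shared slide 1, and the MYC siRNA2 arrays were alone on slide 2, so that slide and group cannot be told apart in both comparisons that involve MYC siRNA2. On slide 1 the control arrays lay in row 1 and the MYC siRNA1 arrays in row 2. Row and group therefore cannot be told apart for MYC siRNA1 against control.

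The first question was how far each siRNA lowered its target. MYC, read by 1 probe that was well above background on all 12 arrays, had a normalised log2 signal of 5.62 ± 0.04 with control siRNA, 3.95 ± 0.07 with MYC siRNA1 and 3.47 ± 0.05 with MYC siRNA2 (mean and SD, n = 4 arrays each). The log2 change was -1.67 with MYC siRNA1, leaving 31.5% of the control signal (95% confidence interval 29.6% to 33.4%; limma adjusted p = 5.71e-12). It was -2.15 with MYC siRNA2, leaving 22.6% (21.3% to 24.0%; limma adjusted p = 1.50e-12). In both comparisons the 4 treated arrays lay below the 4 control arrays, and the exact two-sided permutation p was 0.0286, the smallest that the 70 splits of 4 against 4 arrays allow. The 2 siRNAs differed by -0.48 (limma adjusted p = 4.62e-07, exact permutation p = 0.0286). That difference depended on the scaling: it was -0.05 (limma adjusted p = 0.386) with no scaling between arrays and -0.08 (limma adjusted p = 0.261) with scaling to the spike-in controls.

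**Figure D1:**
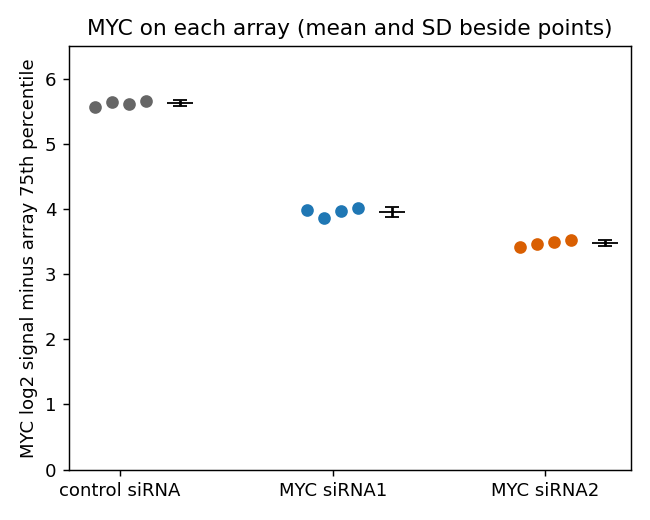
MYC signal on each of the 12 arrays, as log2 processed signal minus the 75th percentile of the array (vertical axis), by siRNA group (horizontal axis). Points are arrays, and the bar beside them gives the mean and SD of the 4 arrays, which are 5.62 ± 0.04, 3.95 ± 0.07 and 3.47 ± 0.05.

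The partners and relatives of MYC moved in different directions. With MYC siRNA1, MXD1 changed by 1.73, MXD4 by 1.56, MNT by 0.63, MXI1 by -0.92, MXD3 by -0.44 and MLX by -0.34 on the log2 scale. With MYC siRNA2 the log2 changes were 0.87 for MXD1, 0.35 for MXD4, -1.37 for MXI1, 0.36 for MXD3 and -0.74 for MLX. MNT, at -0.08, was not called with MYC siRNA2 (limma adjusted p = 0.057). Under 5 other scalings MNT was called higher, from 0.12 to 0.37, and with median centring it turned above 0 without a call. It was called lower with the mean of all probes (-0.31, 2.2e-05), with the other variance model (0.028), and without control replicate 3 (0.0391) or MYC siRNA2 replicate 2 (0.0436). MAX, the binding partner of MYC, changed by -0.78 with MYC siRNA2 (from 4.05 ± 0.04 to 3.27 ± 0.02, SD, n = 4) and by 0.12 with MYC siRNA1. When all probes of a gene were averaged, the small rise of MAX with MYC siRNA1 was -0.02, and the fall of MXD3 was -0.073 and no longer called (limma adjusted p = 0.597). The rise of MAX was also not called with scaling to the spike-in controls (0.080). The difference between the siRNAs was -0.90 for MAX and 0.80 for MXD3 (limma adjusted p = 8.4e-11 and 3.5e-10).

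MYC siRNA1 against control asked which transcripts changed when MYC was lowered by the first siRNA. Of the 14890 genes tested, 5452 were higher and 6548 lower (limma, Benjamini-Hochberg adjusted p below 0.05), or 80.6% in all. The smallest called log2 change was 0.046 in size, and 1153 genes were at least 2-fold higher and 1530 at least 2-fold lower. Of the called genes 45.4% were higher. That share was 57.9% on the authors' scaled values, which moved the median of all genes by 0.17, and 56.9% when the percentile was taken over detected probes, which moved it by 0.15. KRT6B rose most among genes detected in every group, from -3.92 ± 0.34 to 1.58 ± 0.11 (SD, n = 4), a log2 change of 5.50 (limma adjusted p = 1.4e-11). CXCL1 rose by 4.20 (limma adjusted p = 7.9e-12). TNF, APOL6 and KRT6C were not well above background on any control array and were at least 7.86-fold, 6.18-fold and 17.7-fold higher. MS4A15 and BMP6, detected on all control arrays and on none with MYC siRNA1, were at least 4.18-fold and 4.39-fold lower.

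Of the 32 gene lists that were fixed before the data were examined, camera called 14 lower and 6 higher with MYC siRNA1. Beside each camera p below stands the value with an estimated correlation between genes. All 50 ribosome biogenesis genes were lower, with a median log2 change of -1.40 (adjusted p = 1.27e-15, and 0.043 with an estimated correlation). All 38 genes of DNA replication and the G1/S transition were lower (median -1.38, adjusted p = 2.61e-12 and 0.041), as were 30 of 31 mitosis genes (median -1.22, 7.18e-10 and 0.059). The other lists called lower whose call held with an estimated correlation were purine synthesis (15 of 16 lower, median -1.16, adjusted p = 0.049), mitochondrial ribosome and import (42 of 45, -0.9992, 0.047), RNA polymerase I and III (29 of 32, -0.67, 0.041) and translation factors (29 of 30, -0.66, 0.049). Those whose call was lost were pyrimidine synthesis (17 of 18 lower, median -1.0002, adjusted p = 0.059), ribosomal proteins (76 of 77, -0.42, 0.14), oxidative phosphorylation (36 of 41, -0.40, 0.14) and aminoacyl-tRNA synthetases (19 of 21, -0.31, 0.11). It was also lost for the serine and glycine pathway (10 of 15, -0.65, 0.14), glutamine and proline (16 of 20, -0.46, 0.23) and glycolysis (14 of 21, -0.37, 0.32). With the preset correlation, the first of these 3 was no longer called without any of 6 single arrays and the second without any of 2, at adjusted p up to 0.0573 and 0.0529. The first was also lost with quantile normalisation, no scaling and the replicate block (0.0514 to 0.0727), and the second with quantile normalisation and with genes detected on all arrays (0.0516 to 0.141). Glycolysis was lost in 4 settings (0.0527 to 0.212), namely quantile normalisation, the authors' scaled values, the percentile over detected probes and lists without shared members. Among the lists called higher, the interferon response (18 of 24 higher, median 1.35, adjusted p = 0.041) and the CDK inhibitors and genes reported as MYC-repressed (14 of 19, 0.63, 0.049) kept their call with an estimated correlation. Epithelial-mesenchymal genes (15 of 19 higher, 0.66, 0.052), lysosome and autophagy (25 of 33, 0.43, 0.059), cholesterol synthesis (17 of 23, 0.39, 0.25) and the integrated stress and unfolded protein response (16 of 23, 0.58, 0.43) did not. Member counts adjusted over the list alone were the same, except that 2 synthetases were called higher in place of 1.

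The 12 lists not called with MYC siRNA1 had camera adjusted p between 0.0789 and 0.967. Their median log2 changes were -0.41 for polyamines and methionine, -0.27 for the TCA cycle, -0.12 for fatty acid synthesis, 0.01 for the pentose phosphate pathway, 0.03 for p53 targets and 0.15 for hypoxia. They were 0.32 for WNT targets, 0.15 for intestinal differentiation, -0.20 for the MYC network, -0.23 for the RNA interference machinery, -0.26 for reference genes and close to 0 for the 7 tested markers of other cell types. The mean was above 0 for the MYC network (0.03) and the RNA interference machinery (0.06), against medians below 0. For 3 of the 12 lists the sign of the median changed under at least 1 of 6 other scalings, which, quantile normalisation apart, move all genes of an array alike and leave the place of a list among them as it was. Polyamines and methionine were called lower in 2 other settings (0.0199 to 0.0259), and without a filter on dim probes the TCA cycle (0.0370) and reference genes (0.0134) were called lower and WNT targets (0.0484) higher.

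MYC siRNA2 against control asked the same question with the second siRNA. Here 5371 genes were higher and 6998 lower (83.1% called), 958 and 1304 of them at least 2-fold. Of the called genes 43.4% were higher, a share that was 74.3% with no scaling between arrays, 70.2% with scaling to the spike-in controls, 60.8% on the authors' scaled values and 57.3% with the percentile over detected probes. These scalings moved the median of all genes by 0.45, 0.38, 0.25 and 0.20, and the log2 changes given here are relative to the 75th percentile of the array. JAK1 fell from 0.40 ± 0.07 to -3.07 ± 0.15 (SD, n = 4), a log2 change of -3.48 (limma adjusted p = 4.2e-12). CRIM1, SELENOKP3, BEX1 and NOTUM were not well above background on any control array and were at least 5.33-fold, 3.18-fold, 2.61-fold and 3.12-fold higher. SNORA74A and SNORA30, small nucleolar RNAs that were above background on no MYC siRNA2 array, were at least 5.89-fold and 6.69-fold lower.

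With MYC siRNA2 camera called 14 lists lower and 4 higher. All 50 ribosome biogenesis genes were lower (median -1.60, adjusted p = 1.52e-15, and 0.041 with an estimated correlation), and so were all 77 ribosomal proteins (-0.79, 5.69e-16 and 0.11). With an estimated correlation the call also held for mitochondrial ribosome and import (43 of 45 lower, -1.09, adjusted p = 0.041), purine synthesis (15 of 16, -1.04, 0.041), RNA polymerase I and III (31 of 32, -0.94, 0.036), translation factors (30 of 30, -0.88, 0.041) and aminoacyl-tRNA synthetases (21 of 21, -0.72, 0.043). It was lost for the serine and glycine pathway (11 of 15 lower, -0.96, 0.084), oxidative phosphorylation (38 of 41, -0.59, 0.077), glycolysis (16 of 21, -0.58, 0.22), DNA replication (32 of 38, -0.52, 0.11), glutamine and proline (16 of 20, -0.52, 0.12) and pyrimidine synthesis (15 of 18, -0.50, 0.13). It was also lost for mitosis (28 of 31 lower, -0.39, 0.19), whose median was 0.06 with no scaling between arrays and -0.30 relative to all genes with either scaling. The interferon response (19 of 24 higher, 0.70, 0.030) and the CDK inhibitor list (15 of 19, 0.53, 0.041) were called higher with both correlations, and epithelial-mesenchymal genes (14 of 19, 0.49, 0.058) and lysosome and autophagy (26 of 33, 0.23, 0.064) with the preset correlation alone. The 14 lists not called had camera adjusted p between 0.0538 and 0.987, and for 11 of them a median below 0 turned above 0, or the reverse, under at least 1 of these 6 scalings. Their medians were 0.70 for intestinal differentiation (8 of 12 higher), 0.30 for markers of other cell types (5 of 7), 0.24 for WNT targets, -0.43 for the MYC network, -0.36 for polyamines and methionine, -0.33 for the RNA interference machinery and -0.30 for reference genes. They were -0.27 for cholesterol synthesis and for fatty acid synthesis, -0.22 for the stress and unfolded protein response, -0.17 for the TCA cycle, -0.15 for the pentose phosphate pathway and for hypoxia, and -0.048 for p53 targets. WNT targets were called without control replicate 2 (0.0492), and markers of other cell types without MYC siRNA1 replicate 3 or MYC siRNA2 replicate 2 (0.0441 to 0.0498). Other settings called these 2 lists too, as well as polyamines, the TCA cycle, cholesterol synthesis and reference genes when dim probes were not filtered, while glycolysis was lost with quantile normalisation (0.214). Member counts adjusted over the list alone were the same, except for 8 in place of 7 genes of the MYC network called lower.

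**Figure D2:**
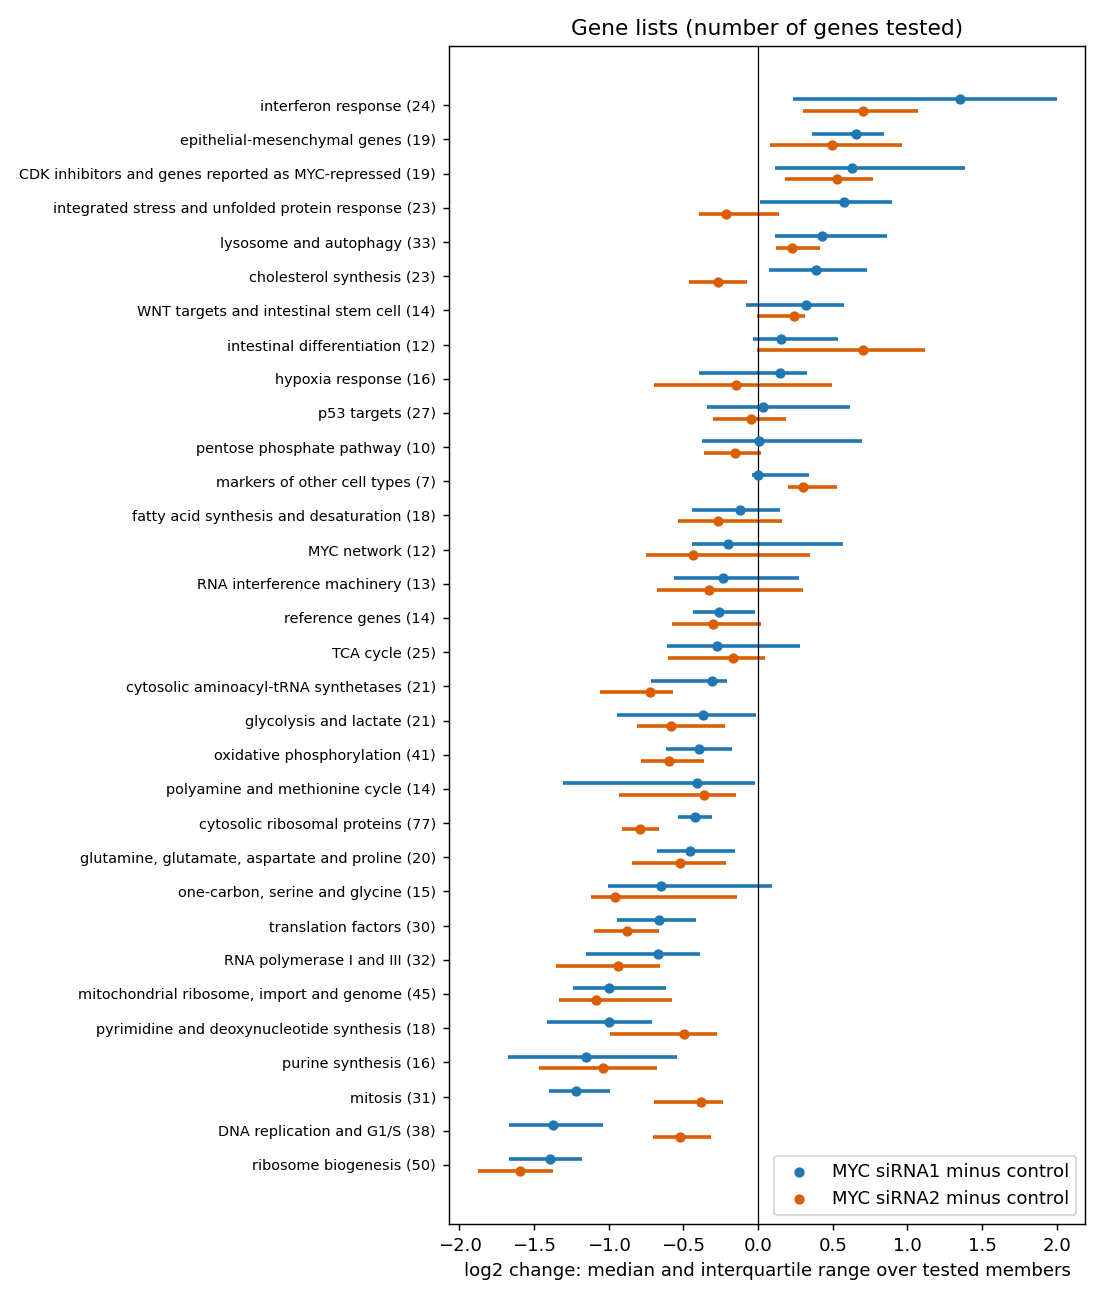
Median log2 change against control of the gene lists (horizontal axis) with MYC siRNA1 and with MYC siRNA2, with the interquartile range of the members. Ribosome biogenesis lay at -1.40 and -1.60, and DNA replication at -1.38 and -0.52.

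The next question was which changes both siRNAs shared. Both called 3607 genes higher and 5087 lower, against 1967 and 3077 expected for independent lists, and 1694 genes were called in opposite directions. At 2-fold or more there were 515 shared rises, 729 shared falls and 6 opposite changes. Because both comparisons used the same control arrays, 3 unchanged groups were simulated 100 times. Their log2 changes against the shared controls had a mean correlation of 0.498 and a mean covariance of 0.0064, with the same sign in 66.7% of genes. At most 1 gene per simulation was called in the same direction by both. With no true change such calls are rare by construction, so this count does not measure what shared controls add to the calls. The observed covariance was 0.429, and the correlation of the log2 changes across genes, which are not independent replicates, was 0.715. With 2 of the control arrays assigned to each siRNA, in the 6 possible ways, the correlation was 0.693 to 0.707, with 3237 to 3273 shared rises and 4745 to 4782 shared falls.

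Ranked by the smaller of both changes, the genes that rose furthest with both siRNAs and were detected on all arrays included BIRC3 (3.87 and 2.90 with MYC siRNA1 and MYC siRNA2), CLIC3 (3.40 and 2.80), B3GALT4 (3.27 and 2.77), SEMA3B-AS1 (3.04 and 2.91) and FBLIM1 (3.30 and 2.64). GBP3 was at least 9.13-fold and 6.44-fold higher, since no control array was above background. Of the 10 genes that fell furthest with both, 8 were small nucleolar RNAs. SNORA48 changed by -3.34 and -4.28, SNORA67 by -3.19 and -4.46 and SNORA62 by -3.20 and -4.0012 (limma adjusted p of 2.3e-12 or less). CTRL, above background on all control arrays and on no other, was at least 9.38-fold and 12.5-fold lower. Within the lists, WDR3 changed by -2.63 and -2.61, BOP1 by -2.46 and -2.82, PPAT by -2.10 and -1.97, HK2 by -2.56 and -3.91, ODC1 by -1.30 and -1.09, CDK4 by -1.65 and -2.09, IFIT2 by 2.82 and 1.67 and CDH1 by 1.72 and 1.71.

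**Figure D3:**
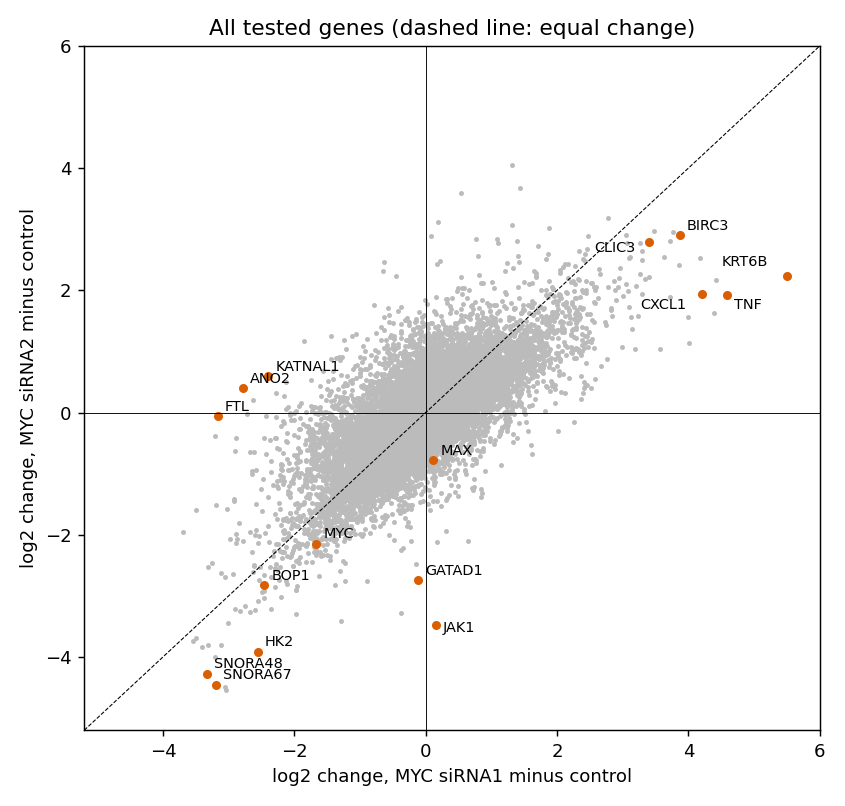
Log2 change with MYC siRNA1 (horizontal axis) against log2 change with MYC siRNA2 (vertical axis), 1 point per gene tested, with named genes marked. The correlation across genes was 0.715, and JAK1 (0.15 and -3.48) and FTL (-3.17 and -0.06) lay away from the diagonal.

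The direct comparison of MYC siRNA2 with MYC siRNA1 asked where the 2 reagents against the same target differed. It called 4941 genes higher and 6996 lower, 752 and 455 of them at least 2-fold, and 41.4% of the called genes were higher. That share was 83.0% with no scaling and 81.1% with scaling to the spike-in controls, which moved the median of all genes by 0.43 and 0.40. FTL, the ferritin light chain, was 6.80 ± 0.01 with control siRNA, 3.63 ± 0.05 with MYC siRNA1 and 6.74 ± 0.01 with MYC siRNA2 (SD, n = 4), a difference of 3.11 (limma adjusted p = 6.9e-14). Its change with MYC siRNA2, -0.059 (0.056), was not called and had the other sign under 6 scalings, from 0.079 to 0.39. It was called lower in 3 settings that kept the scaling but changed the test (0.0017 to 0.037), and without MYC siRNA1 replicate 2 (0.0452) or 4 (0.0352). ANO2 differed by 3.18 and KATNAL1 by 3.0006, each falling with MYC siRNA1 (-2.78 and -2.40) and rising with MYC siRNA2 (0.40 and 0.60). JAK1 differed by -3.63 and GATAD1 by -2.63. With MYC siRNA1 neither was called against control (JAK1 0.15, limma adjusted p = 0.084, and GATAD1 -0.12, 0.061), but leaving out 1 array called each of them, at adjusted p of 0.0196 to 0.0421 for JAK1 (2 arrays) and 0.0199 to 0.0470 for GATAD1 (3 arrays). Another 6 settings called JAK1 higher, by 0.15 to 0.32, and 4 called GATAD1 lower, the replicate block among them (0.0296).

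Camera called 3 lists higher and 4 lower with MYC siRNA2 than with MYC siRNA1, none of them with an estimated correlation. DNA replication was higher by a median of 0.89 (34 of 38 genes higher, adjusted p = 5.98e-13, and 0.061 with an estimated correlation) and mitosis by 0.86 (30 of 31, 8.6e-13 and 0.17). Pyrimidine synthesis was higher by 0.30 (13 of 18, 0.00314 and 0.34). Cholesterol synthesis was lower by a median of -0.69 (18 of 23, 0.000427 and 0.34) and the stress and unfolded protein response by -0.50 (21 of 23, 0.000542 and 0.42). Ribosomal proteins (-0.36, 68 of 77 lower, 1.61e-08 and 0.38) and aminoacyl-tRNA synthetases (-0.34, 17 of 21, 0.00314 and 0.34) were lower on the main scale, by -0.26 and -0.24 relative to the median of all genes. With no scaling these relative shifts were the same by construction, since all genes of an array move alike, but neither list was called (0.0645 and 0.111), and with spike-in scaling the synthetases were not (0.0600). The medians of ribosomal proteins and synthetases themselves turned above 0, to 0.071 and 0.089 with no scaling and to 0.039 and 0.058 with spike-in scaling. With quantile normalisation the relative shift of ribosomal proteins was -0.056 and not called (0.0541). The interferon response differed by -0.69 and was not called (adjusted p = 0.063), though it was called lower without MYC siRNA2 replicate 4 (0.0455) and in 9 other settings (5.09e-05 to 0.0496). The 25 lists not called had camera adjusted p of 0.0630 to 0.989, and for 19 of them the sign of the median changed under at least 1 of the same 6 scalings. Besides the interferon response, the MYC network was called lower with scaling to the spike-in controls (0.0408), and glutamine and proline (0.0496) and RNA polymerase I and III (0.0301) were called lower with the mean of all probes. Member counts adjusted over the list alone were the same, except for 1 more gene called lower among the synthetases, the TCA cycle and the interferon response, 1 more higher in the interferon response and 1 fewer higher in the mitochondrial list.

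**Figure D4:**
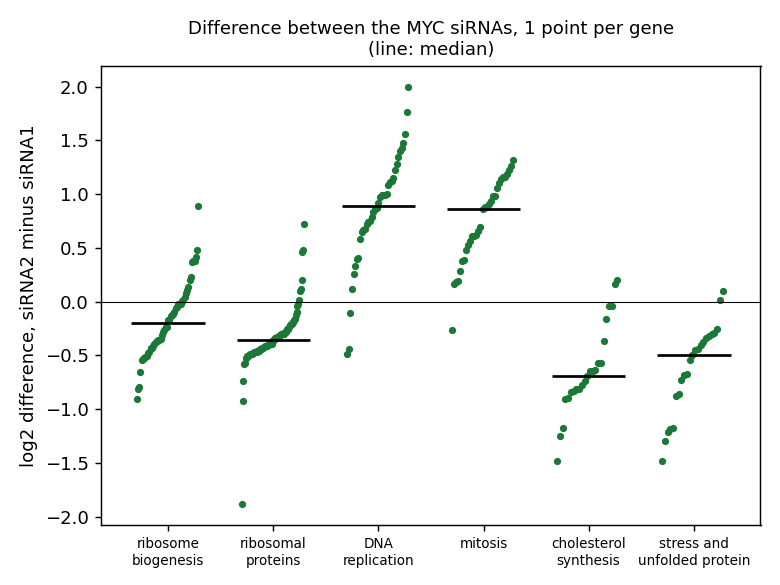
Log2 difference, MYC siRNA2 minus MYC siRNA1 (vertical axis), of the members of 6 gene lists (horizontal axis), 1 point per gene with the median as a line. DNA replication had a median of 0.89 and cholesterol synthesis of -0.69.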

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

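The tests of a slide effect and of a graded effect of MYC on the cell cycle lists, and the tests on genes that moved with a single siRNA, with their counts under other scalings, were chosen only after the results were seen, and so were the classes of short RNA. The remaining predictions were written before their tests were run.

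Of 375 groups of 4 values tested, 17 held a value far from the other 3 by Dixon's criterion, where 18.75 would be expected by chance. In the control group these were KATNAL1 (3.57), ODC1 (7.83) and NDRG1 (5.29) in replicate 1, EIF3B (6.78) and TFRC (6.11) in replicate 2 and DNAJB9 (3.67) in replicate 4, as normalised log2 signals. With MYC siRNA1 they were CLIC3 (4.34) and CDC20 (3.26) in replicate 4 and HPRT1 (3.39) in replicate 3. With MYC siRNA2 they were JAK1 (-3.30) and SNORA38B (-5.68) in replicate 2, KRT6C (-2.16) in replicate 3, and APOOP5 (-1.17), TWNK (-0.84) and TOMM40 (1.31) in replicate 4. Among the array measures, 49.6% of spots were well above background in MYC siRNA2 replicate 1, and the mean log2 spike-in signal was 11.90 in control replicate 2.

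The effects of both siRNAs differed, by the direct comparison, in 7 lists: DNA replication (0.89), mitosis (0.86), pyrimidine synthesis (0.30), ribosomal proteins (-0.36), aminoacyl-tRNA synthetases (-0.34), the stress and unfolded protein response (-0.50) and cholesterol synthesis (-0.69), as median log2 differences, MYC siRNA2 minus MYC siRNA1. None of these calls held with an estimated correlation. The medians of ribosomal proteins and aminoacyl-tRNA synthetases were above 0 with no scaling (0.071 and 0.089) and with spike-in scaling (0.039 and 0.058).

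In signal outside the comparisons, the 75th percentile relative to the spike-in probes was higher by 0.38 with MYC siRNA2 than with control, or 1.30-fold, and with MYC siRNA1 the difference was -0.02. Control arrays varied by an SD of 0.04. MYC siRNA2 was alone on slide 2, so that slide and siRNA cannot be told apart here, and no biological explanation was tested. Among 7318 detected probes without a gene name, 2451 were called in the same direction by both siRNAs, 1344 higher and 1107 lower.

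The number of called genes was larger than other splits of the arrays gave. For MYC siRNA1 against control, 8-array fits called 11902 genes and 1 of the 35 splits, the real one, reached that, the highest other count being 0. For MYC siRNA2 against control (12512) and between the siRNAs (11812) the result was again 1 of 35, with 0 as the highest other. There the real split is also the split by slide, and for MYC siRNA1 against control it is also the split by row. In each case 1 of 35 is the smallest share that these splits allow. The other splits mixed the groups, so the real difference widened their spread and made low counts likely. These counts alone therefore do not exclude chance. For genes called in the same direction by both siRNAs, 1 of 100 groupings of the 12 arrays, the real one among them and the others drawn, reached 8694, and the highest other was 7345.

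Counts of lists do not exclude chance. The real splits gave 19, 19 and 8 lists for the comparisons in the same order, and 7, 10 and 6 of the 35 splits gave as many, the highest others being 19, 21 and 9. Of these splits, looked at after the counts were seen, 6, 9 and 5 kept 3 of 4 arrays of each group together and so carried part of the real difference. Splits that mixed 2 and 2 arrays gave at most 2, 1 and 1 lists. The largest median of a list was 1.40, 1.60 and 0.89 in size for the real splits, against at most 0.76, 0.81 and 0.49 for the others.

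Genes of DNA replication and mitosis fell less with MYC siRNA2 than with MYC siRNA1, although MYC itself fell further on the main scale. A difference between arrays that follows signal brightness is argued against: the median difference of the 69 genes lay at percentile 100 of 10000 random lists of the same brightness, whose highest median was 0.09. An effect graded by the fall of MYC would put the median difference at 0 or below. It was 0.87, and 0.86 to 1.29 in 8 other settings. In each of these the 4 MYC siRNA2 arrays lay above the 4 MYC siRNA1 arrays, and MYC was not higher with MYC siRNA2 (-0.48 to -0.052). The pattern was picked because of this difference, so these values restate it and cannot decide on a graded effect. MYC was read as RNA by 1 probe, and MYC siRNA2 on slide 2 alone. A slide or scan effect on these probes cannot be told apart from the siRNA, since no slide held both siRNAs, and the 7 spike-in probes, whose differences between slides had an SD of 0.0573, are not these probes. Effects of a single siRNA on other targets may contribute and were not tested for this pattern.

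Small nucleolar RNAs were among the largest falls with both siRNAs: the 87 tested RNAs of the SNORA class had medians of -1.13 and -1.48, with 72 and 80 called lower, and the 100 of the SNORD class -1.01 and -1.35, with 90 and 97. The 16 tested RNAs of the SCARNA class, kept apart from these and from the other short RNAs below, had medians of -1.20 and -1.72, with 12 and 15 called lower. The RNA was column-purified and amplified. Whether these probes read the mature short RNAs or longer transcripts that contain them was not tested. Poorer recovery of short RNA stays open: 21 other short RNAs had a median of -0.41 with MYC siRNA1, and of -1.01 with MYC siRNA2. They were the SNAR family, vault RNAs, RMRP, RPPH1, RN7SK, RN7SL1, small nuclear RNAs of the RNU and RNVU type, and TERC. The prediction had not named TERC, which changed by -1.19 and -1.70. The 21 RNAs may themselves respond to the fall of MYC, and members of a family are not independent, so they are no neutral reference for recovery. Against 0.5 times the medians of all 187 small nucleolar RNAs, -1.02 and -1.38, the first was the smaller fall and the second the larger. A fall of the host transcripts stays open too: the 97 tested hosts had medians of -0.496 and -0.695, on both sides of the limit of -0.5 set beforehand, and 122 and 134 of 171 small nucleolar RNAs fell below their host. The shortest tested gene whose coordinates contain the RNA counted as its host, on either strand. Some hosts may therefore not be the transcript that holds the RNA. Of the hosts, 75 and 85 were called lower. The rank correlation between the changes of RNA and host was only 0.29 and 0.26 across these pairs, which share hosts. A response of these RNAs to the fall of MYC is a further candidate explanation that the design cannot part from these.

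Some genes moved strongly with 1 siRNA only, defined as at least 4-fold with that siRNA and by less than 0.25 on the log2 scale with the other. With MYC siRNA1 there were 13 falls and 2 rises, and with MYC siRNA2 5 falls, JAK1 and GATAD1 among them, and 4 rises, which include NOTUM. NOTUM was well above background on no control array, so a 4-fold rise was not measured for it. Its change with MYC siRNA1 was 0.675 without control replicate 1, beyond the limit. Under 6 other scalings there were 12 to 17 falls and 1 to 5 rises with MYC siRNA1, and 3 to 5 falls and 2 to 13 rises with MYC siRNA2, and the change of JAK1 with MYC siRNA1 reached 0.32, beyond the limit. Knockdown of unintended targets may explain the falls but stays open: it would give mostly falls, and the share was 86.7% for MYC siRNA1 (73.7% to 94.4% under the other scalings) but 55.6% for MYC siRNA2 (18.75% to 71.4%), and the sequences are unknown. Among all genes called at 2-fold or more, 1530 fell and 1153 rose with MYC siRNA1, and 1304 fell and 958 rose with MYC siRNA2. The shares rest on few genes, and the rule asked for mostly falls with both siRNAs, though unintended targets may differ between them. A slide or scan effect cannot be told apart from the siRNA for the 5 falls with MYC siRNA2, nor for the lack of change with MYC siRNA2 of the 13 genes that fell with MYC siRNA1, since those values were read on slide 2 against controls on slide 1.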

How the results depend on the processing

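Of the alternatives below, scaling to the spike-in controls, the percentile over detected probes and normexp on median signals were chosen after seeing the data. Normexp on mean signals and a slide block were not run, because the column is missing and slide 2 held 1 group alone.

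Over all alternatives, 7033 values of named genes kept their side of the threshold without a reversal, 30 newly passed it, 13 no longer passed it and 16 reversed. A change of sign counted as a reversal only where the main or the other value was called. For lists these numbers were 2365, 79, 51 and 1, and among the main counts and MYC values 427 stayed, 32 counts changed by more than 1.5-fold and 2 values no longer passed the threshold.

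With no scaling, MYC siRNA2 against control gave 9355 genes higher and 3237 lower, MYC siRNA2 against MYC siRNA1 gave 9859 and 2014, 2858 genes were lower with both siRNAs, and the MYC difference was -0.052. With scaling to the spike-in controls these were 8606 and 3646, 9256 and 2152, 3165 and -0.083. These 2 settings keep the brighter signal of the MYC siRNA2 arrays, which the 75th percentile removes, so the change follows from their construction. On the authors' scaled values 5479 genes were higher with both siRNAs, and without a filter on dim probes 8182 were higher with MYC siRNA1. The mean of all probes gave 7 lists lower with MYC siRNA2 than with MYC siRNA1. The cause of these 3 was not tested.

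Requiring a 2-fold change as well left 1153 higher and 1530 lower with MYC siRNA1, 958 and 1304 with MYC siRNA2, 752 and 455 between the siRNAs, and 515 and 729 with both, by construction fewer. An estimated correlation between genes left 2 lists higher and 6 lower with MYC siRNA1, 2 and 6 with MYC siRNA2, and 0 and 0 between them. Fry, which does not compare a list with other genes, gave 11 higher with MYC siRNA1, 8 higher and 24 lower with MYC siRNA2, and 5 and 25 between them. For the epithelial-mesenchymal list, whose median difference relative to all genes was 0.091, camera gave the direction up without a call (adjusted p = 0.989) and fry, which works on the list alone with its mean of -0.13, called it down (2.47e-07).

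The log2 change of MNT with MYC siRNA2 was -0.083 and reversed to 0.12 with quantile normalisation, 0.37 with no scaling, 0.17 on the authors' scaled values, 0.12 with the percentile over detected probes and 0.30 with spike-in scaling. That of FTL, -0.059, reversed to 0.33, 0.39, 0.19, 0.14 and 0.32 under the same settings in that order, and to 0.079 with median centring and 0.096 with normexp. Both lay near 0, where a shift of all genes by the scaling changes the sign. Median centring moved all genes by 0.14, which turned MNT above 0 as well, without a call. Quantile normalisation does not move all genes alike, and the cause there, and for FTL with normexp, was not tested. MLX differed between the siRNAs by -0.41, and by 0.022 with no scaling. With normexp, TNF was at -0.062 and APOL6 at -0.022 with MYC siRNA2, against rises in the other settings, but neither was above background on any control array, so the size of these changes was not measured. MAX with MYC siRNA1 was 0.12, and -0.019 with the mean of all probes. The cause for TNF, APOL6 and MAX was not tested.

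With the replicate block the counts were 5471 higher and 6531 lower with MYC siRNA1, 5347 and 6986 with MYC siRNA2, and 4946 and 7022 between them. It changed single calls: the serine and glycine list with MYC siRNA1 was lost (adjusted p = 0.0727), and markers of other cell types with MYC siRNA2 (0.0330) and GATAD1 with MYC siRNA1 (0.0296) were called.

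Leaving out each array in turn gave 5331 to 5457 higher and 6385 to 6542 lower with MYC siRNA1, 5215 to 5392 and 6872 to 7029 with MYC siRNA2, and 4772 to 4918 and 6858 to 6989 between them. Both siRNAs shared 3494 to 3591 rises and 4974 to 5077 falls, and the MYC change was -1.69 to -1.63, -2.17 to -2.13 and -0.51 to -0.46. The call of the serine and glycine list with MYC siRNA1 was lost without any of 6 arrays (adjusted p up to 0.0573), namely control replicates 2 and 4, MYC siRNA1 replicate 4 and MYC siRNA2 replicates 1, 2 and 4. That of the glutamine list was lost without control replicate 4 or MYC siRNA1 replicate 4 (up to 0.0529).

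Dim signal limits the genes given as "at least". The smallest changes limit the rest: in simulated data with 14890 genes, 26% of 1.1-fold changes were recovered for MYC siRNA1 against control.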

Other observations

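The 4 gene lists and the genes in this part were chosen after the data were seen, some of them because their members were among the largest changes, so no test of the lists is given and no explanation was tested.

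Genes known as targets of NF-kappaB were mostly called higher with both siRNAs, 17 of 19 each, with median log2 changes of 1.64 and 0.81. The median difference between the siRNAs was -0.75, with 18 of 19 lower with MYC siRNA2. CXCL8 changed by 4.18 and 2.54, CCL20 by 3.9956 and 1.57, and TNIP1 by -1.74 and 0.53. Of 13 keratins in the list, 11 and 10 were called higher, with medians of 1.33 and 1.02. Of 14 genes of antigen presentation by MHC class I, 11 were called higher and 3 lower with each siRNA, with medians of 0.65 and 0.38.

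Of 12 iron storage and uptake genes, 5 were called higher and 5 lower with MYC siRNA1, and 3 higher and 6 lower with MYC siRNA2. TFRC was lower with both (-0.97 and -1.64), FTL changed by -3.17 with MYC siRNA1, and HMOX1 changed by 1.53 and -0.15.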
